A study of Mus musculus with 15 samples.

How the data were processed

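RNA was measured in whole testes of C57BL/6J mice of 3 genotypes, with 5 samples each: wild type (WT), ARLmon/Y males, whose androgen receptor carries a change in the ligand-binding domain meant to stop those domains from pairing, and AR-/Y males, which lack a working receptor. Per the labels' protocols, testes were snap-frozen, RNA was purified on columns, and libraries were made with a strand-specific mRNA kit and sequenced on an Illumina HiSeq4000. The submitters' processing notes name FastQC 0.11.7, HISAT2, SAMtools 1.5, HTSeq, DESeq2 and the mouse genome build mm10, without saying which step used what. The gene annotation and the strand setting of the counting are not given in the sources used here.

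The authors deposited 3 tables of raw read counts per gene, each holding the 10 libraries of 2 genotypes. They list 28176, 27538 and 28133 genes, and the smallest total of a listed gene over its 10 libraries was 2 counts. A library held the same counts in both tables that contain it, so the tables were joined by gene symbol into 29049 genes and 15 libraries, and a gene missing from a table was set to 0 there. The authors also deposited a table of log2 FPKM values made from aligned reads, per the file headers, in which zeros stand as small values set by a rule that the header does not give. It was turned back to FPKM and used as an alternative only.

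Each column was tied to its genotype through the library codes in the header of the FPKM table, which give no replicate number. The letters a to e within a genotype are therefore names without order, and no library of one genotype is paired with a library of another. Pairs of libraries of the same genotype differed by more than sampling noise, with a chi-square per degree of freedom of at least 2.51, so that no library was counted as deposited in duplicate. Nothing in the labels says that the 5 samples of a genotype came from separate mice, so p-values measure only the spread between these samples, which may be technical.

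Total counts ran from 5330682 to 55136488 in WT, from 11821149 to 27937417 in ARLmon/Y and from 11884581 to 12954681 in AR-/Y. Low-count genes were removed with edgeR's filterByExpr, which left 18719 genes and at least 99.1% of the counts of each library. Libraries were scaled by TMM, with mean factors of 0.746 in WT, 1.05 in ARLmon/Y and 1.27 in AR-/Y. All 15 libraries entered one fit of edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with genotype as the only term, and 3 contrasts were tested. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The coefficient of variation between libraries beyond counting error was 26.2%. CPM values given as mean ± SD were computed with the TMM scaling. Each SE is the absolute log2 fold change divided by the square root of the test's F statistic. Whole testis was measured, so each value is a share of the RNA of all its cell types, and a change in the cell types present moves it as a change within a cell would.

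Before the data were examined, 25 gene lists with 431 distinct genes, of which 400 were tested, were fixed from textbook knowledge of the mouse testis. They cover the somatic and germ cell types, steroid and cholesterol synthesis, junctions, stress, cell cycle and retinoid genes, and 4 tissues outside the testis (epididymis and duct epithelium, adipocyte, skeletal muscle, red blood cell). Lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 25 lists of a comparison. For each list the number of members past the threshold was counted over all genes tested and adjusted over the list alone. List scores are the mean log2 CPM of a list's genes in a library. Lists of liver genes and of granulosa cell genes were added after the data had been seen.

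The genes named in the text follow a rule fixed before the data were examined. It takes Ar, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups do not overlap, with a mean of at least 5 CPM in the higher group and no predicted-gene symbol. It adds the 3 members of each list with the smallest p, those of the tissues outside the testis only where they passed the threshold, and 14 fixed genes (Rhox5, Insl3, Amh, Star, Cyp17a1, Hsd17b3, Hsd3b6, Prm1, Tnp1, Sycp3, Zbtb16, Gdnf, Cirbp and Rbm3). Any other gene is said to have been chosen after its values were seen. Where every library of a group held 0 counts, a fold is given against 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval. Such bounds cover counting error only. Gene positions are from GENCODE vM21 on mm10, in which 94.3% of the tested symbols were found.

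Reads of near-identical genes (Hsd3b1 and Hsd3b6, the Klk1b family, the globins) cannot be told apart without the counting settings, and values of these genes are uncertain. The same holds for genes and their antisense partners in the stretches where they overlap. Insl3, a Leydig cell hormone on the fixed list, shares 64.9% of its 623 exonic bases with Jak3, had 177 counts in all WT, 15 in all ARLmon/Y and 23 in all AR-/Y libraries, and did not pass the filter. No direction is given for it.

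The count test was tested on simulated counts drawn from the real means and library sizes, with the real filter. Of genes changed by a fold of 1.5, 2 and 4, the fit recovered 11.9%, 52.2% and 86.4% in ARLmon/Y against WT (16770 genes), 13.4%, 56.7% and 84.8% in AR-/Y against WT (16731 genes), and 22.4%, 67.2% and 98.5% in ARLmon/Y against AR-/Y (15940 genes). Unchanged genes called were 5, 8 and 8, or 4.76%, 7.21% and 6.02% of the calls. Camera with the preset correlation called 1, 2 and 1 lists, where 1 had been shifted, and the shifted list was among them each time. Both simulated groups started from the same means, and 67, 67 and 66 genes with higher counts were changed at these folds. In the data 76.1%, 89.15% and 74.01% of the genes were called, so scaling error when most genes change is not covered. Genes were drawn independently, so correlation between the genes of a list is not covered either.

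The alternatives were DESeq2's size factors in edgeR, no scaling beyond total counts, scaling on the Sertoli cell list, no low-count filter, DESeq2 1.42.0, a fit of only the 2 groups compared, an added threshold of 1 on the log2 fold change, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, limma with no FPKM filter, an estimated correlation in camera, and leaving out each library in turn. Leaving out ARLmon/Y library a and AR-/Y library a together was added after the data had been seen.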

Results

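Gene expression was measured by mRNA sequencing in whole testes of mice of 3 genotypes, with 5 libraries each: wild type (WT), ARLmon/Y, whose androgen receptor carries a change in its ligand-binding domain meant to stop those domains from pairing, and AR-/Y, a knockout of the receptor. The androgen receptor is the transcription factor through which testosterone acts, and in the testis it works in Sertoli, peritubular and Leydig cells. The comparisons ask how the altered and the absent receptor change the testis against WT, and how the 2 mutants differ from each other. Total counts per library ran from 5330682 to 55136488 in WT, from 11821149 to 27937417 in ARLmon/Y and from 11884581 to 12954681 in AR-/Y.

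The libraries separated by genotype. On the first principal component, which held 90.1% of the variance, the WT libraries lay from -201 to -191, the AR-/Y libraries from 188 to 250, and 4 ARLmon/Y libraries between them from -86.7 to -29.7. ARLmon/Y library a stood apart from these 4 at 91.1, towards the AR-/Y libraries. Albumin mRNA (Alb, made by the liver) reached 2025 CPM in AR-/Y library a and at most 1.28 CPM in every other library. Alb was chosen after its values were seen.

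Ar, the altered gene (chromosome X, 98148769 to 98323215 in mm10), was read in every library of all 3 genotypes. Its level was 15.6, 18.9, 15.2, 16.7 and 16.01 CPM in WT libraries a to e, 105, 50.5, 48.2, 55.9 and 51.8 CPM in ARLmon/Y, and 33.8, 35.4, 35.3, 37.6 and 36.9 CPM in AR-/Y. Counts over the whole gene do not separate the altered or deleted part from the rest, so these levels check nothing about the labels. Ar was 3.77-fold higher in ARLmon/Y than in WT (62.3 ± 24.2 against 16.5 ± 1.49 CPM, SD, n = 5 each, log2 fold change 1.91 with SE 0.19, edgeR's quasi-likelihood test, adjusted p = 1.1e-06) and 2.16-fold higher in AR-/Y (35.8 ± 1.48 CPM, log2 fold change 1.11 with SE 0.19, adjusted p = 3.5e-05). Scaled on the Sertoli cell list, the AR-/Y change turned to -0.46.

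In ARLmon/Y testes, transcripts of the late steps of sperm formation fell and most of those of steroid and cholesterol synthesis rose against WT. Prm1 and Tnp1, which package the DNA of elongating spermatids, fell 16.1-fold (150 ± 119 against 2424 ± 953 CPM, SD, n = 5 each, log2 fold change -4.01, SE 0.69) and 10.8-fold (log2 fold change -3.43, SE 0.64), respectively (edgeR's quasi-likelihood test, adjusted p = 1.1e-04 and 2.3e-04). Star, which carries cholesterol into mitochondria, rose 13.8-fold (978 ± 312 against 70.9 ± 18.9 CPM), and Lhcgr, the receptor for luteinizing hormone, rose 49.7-fold (325 ± 178 against 6.53 ± 2.55 CPM). Rhox5, an androgen-driven homeobox gene of Sertoli cells, fell 6.71-fold (2.51 ± 0.641 against 16.8 ± 4.91 CPM), and Hsd3b6 and Hsd17b3, enzymes of testosterone synthesis in adult Leydig cells, fell 14.3-fold and 6.57-fold. For Prm1, Star, Lhcgr, Rhox5 and Hsd3b6 all 5 ARLmon/Y libraries lay on one side of all 5 WT libraries. Prm1 (chromosome 16, 10796326 to 10805839 in mm10) ran from 42.5 to 345 CPM against 1266 to 3539 CPM. Lhcgr (chromosome 17, 88716481 to 88791990) ran from 198 to 627 CPM against 3.28 to 9.14 CPM. Tnp1 lies on chromosome 1 (73015074 to 73015909), Star on chromosome 8 (25806555 to 25815982), Rhox5 on chromosome X (37804842 to 37808876), Hsd3b6 on chromosome 3 (98805504 to 98814443) and Hsd17b3 on chromosome 13 (64058266 to 64089230).

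The fall deepened with the stage of germ cell development. All 25 measured genes of the elongating spermatid list fell (median log2 fold change -3.11), as did 25 of 26 of the round spermatid list (-1.78, with Tssk3 at -2.84 and Crem at -1.21). So did 15 of 22 of the late pachytene and diplotene list (-0.97, with Calr3 at -2.80 and Cdc25c at -1.49). The counts were equal when adjusted over the list alone. The 3 lists passed camera with adjusted p = 6.1e-07, 8.0e-05 and 8.2e-04, and adjusted p = 0.752 with an estimated correlation. Earlier germ cells differed from this. Of 25 genes of meiotic prophase 11 rose and 6 fell (median 0.22, or -0.54 scaled on the Sertoli cell list and -0.02 with DESeq2's size factors). Of 22 spermatogonial genes 13 rose and 3 fell (0.77, or -0.05 scaled on the Sertoli cell list). Neither list passed camera (adjusted p = 0.677 and 0.239). Prdm9, which marks sites of meiotic recombination, was at 1.09, Syce2 of the synaptonemal complex at -1.78, and the spermatogonial genes Foxo1 and Stra8 at 1.69 and 1.29 (edgeR's quasi-likelihood test, adjusted p from 1.9e-07 to 7.9e-06). The call of Prdm9 ended scaled on the Sertoli cell list (0.27). Sycp3 was at 0.49 (adjusted p = 0.0349 by edgeR's quasi-likelihood test), a call that ended with DESeq2 (0.27) and its size factors in edgeR (0.25), and the value turned to -0.26 scaled on the Sertoli cell list. The Sycp3 call also ended without any one of WT libraries c and d and ARLmon/Y libraries b, c and d (0.37 to 0.49, adjusted p from 0.0540 to 0.0913 by edgeR's quasi-likelihood test). ARLmon/Y library a was the lowest of its group in the stages from meiotic prophase on, with a late pachytene score of 5.57 mean log2 CPM against 7.15 to 7.59 in the other 4, and the highest in spermatogonia (3.71 against 2.99 to 3.38).

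**Figure D1:**
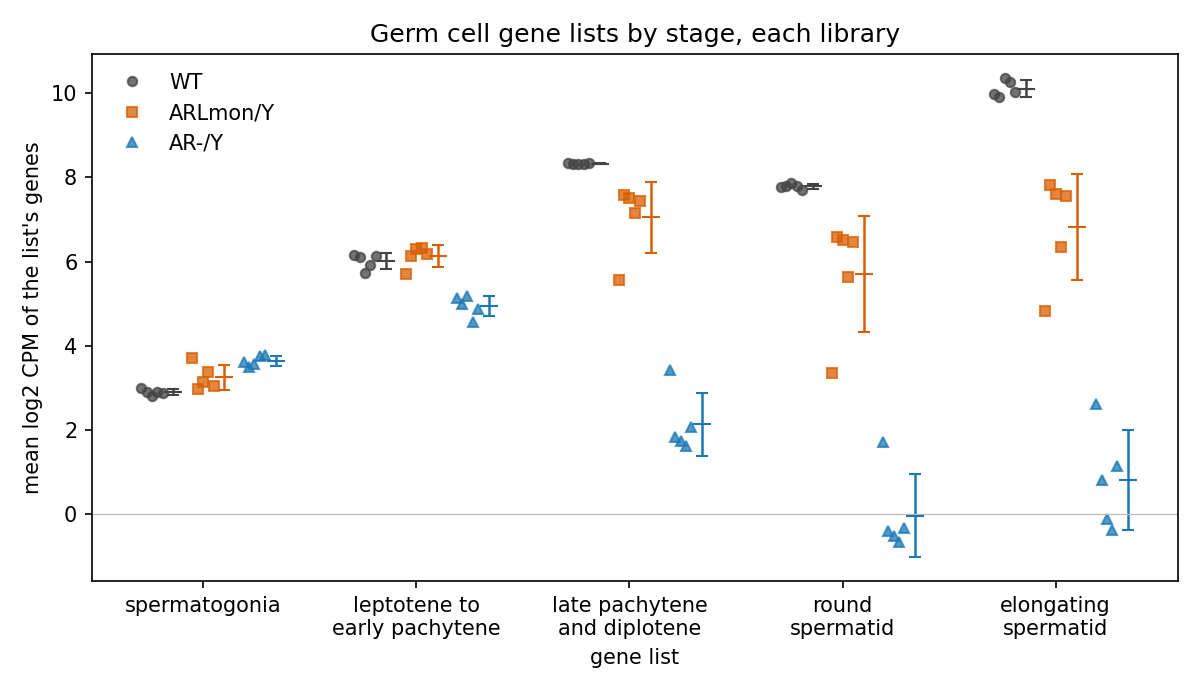
Mean log2 CPM of the genes of 5 germ cell lists (vertical axis) in each library, by genotype (WT circles, ARLmon/Y squares, AR-/Y triangles), with the group mean and SD as bars beside the points, n = 5. The elongating spermatid score was 10.1 ± 0.192 in WT, 6.83 ± 1.26 in ARLmon/Y and 0.818 ± 1.19 in AR-/Y, whereas the spermatogonia score rose from 2.90 ± 0.0652 in WT to 3.65 ± 0.115 in AR-/Y, a direction that turns when libraries are scaled on the Sertoli cell list.

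Of the 14 genes of steroid synthesis, 11 rose and 3 fell, over all genes and adjusted over the list alone (median 2.17, camera, adjusted p = 0.0114, and adjusted p = 0.752 with an estimated correlation). Cyp11a1, which cuts the cholesterol side chain, rose by 4.42 (2098 ± 1060 against 98.2 ± 10.6 CPM), Cyp17a1 by 2.87 and Akr1c14 by 3.12 on the log2 scale. The list's call ended without scaling beyond total counts (adjusted p = 0.135 by camera). Cholesterol synthesis and uptake showed 19 of 22 genes higher and 1 lower, or 20 higher adjusted over the list alone (median 2.24, camera, adjusted p = 6.5e-06, and adjusted p = 0.752 with an estimated correlation). Examples were Hsd17b7 (log2 fold change 3.88, SE 0.22), Msmo1 (3.60, SE 0.21), both enzymes of the pathway's last steps, and Scarb1 (2.49, SE 0.15), the receptor that takes up cholesterol from high-density lipoprotein. Of the fetal or immature Leydig cell list 13 of 14 genes rose and none fell, also adjusted over the list alone (median 2.06, camera, adjusted p = 1.8e-04, and adjusted p = 0.752 with an estimated correlation), among them Hsd3b1 at 3.74, whose reads may be shared with Hsd3b6. The adult Leydig cell list split into 6 higher and 6 lower of 16, or 7 and 6 adjusted over the list alone, and did not pass (median 0.30, or -0.55 scaled on the Sertoli cell list, mean -0.11, with camera pointing down, adjusted p = 0.651), with Lhcgr at 5.64 and Hsd3b6 and Hsd17b3 at -3.83 and -2.72.

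Transcripts of most other somatic cells rose. Of 30 Sertoli cell genes 23 rose and 2 fell (median 0.96), and of 19 macrophage and antigen presentation genes all rose (1.80). Of 13 endothelial genes 11 rose and none fell (1.94), and of 18 extracellular matrix genes 15 rose and 1 fell (1.71). Camera gave adjusted p = 0.00122, 7.1e-05, 2.2e-04 and 1.8e-04, and the counts were equal adjusted over the list alone. None of these 4 lists passed camera with an estimated correlation (adjusted p = 0.752). Inha, the inhibin alpha subunit of Sertoli cells, rose 15.6-fold (1034 ± 393 against 66.6 ± 6.63 CPM), and Col3a1 6.77-fold and Pecam1, an endothelial adhesion molecule, 5.97-fold. Ptgds, a prostaglandin D synthase on the Sertoli cell list, went the other way (log2 fold change -5.47, SE 0.25, 4.37 ± 1.42 against 197 ± 20.8 CPM). Of the 12 androgen-responsive Sertoli genes 5 rose and 5 fell (median 0.03, mean -0.29, camera, adjusted p = 0.560), and the median turned to -0.21 with DESeq2's size factors and to -0.72 scaled on the Sertoli cell list. The remaining lists did not pass. They were peritubular myoid cell (0.69), lymphocyte (0.53), junctions of the blood-testis barrier (0.20), heat shock proteins (0.26), p53 targets (1.01), mitotic cell cycle (0.29), retinoid metabolism (0.86), epididymis (-0.98), adipocyte (-0.44), skeletal muscle (-0.30) and red blood cell (0.44, where the test pointed down), with adjusted p from 0.108 to 0.887 by camera. Of these medians only those of p53 targets and epididymis kept their sign under all 3 other scalings, and the p53 list passed scaled on the Sertoli cell list and with no low-count filter (adjusted p = 0.0379 and 0.0164 by camera).

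Among single genes, Sfrp4, a secreted inhibitor of Wnt signalling, had the largest rise of the named genes by the fitted log2 fold change (130 ± 17.4 against 0.358 ± 0.334 CPM, log2 fold change 9.13, SE 0.49, edgeR's quasi-likelihood test, adjusted p = 1.0e-08). Akr1d1, a bile acid and steroid reductase, had 1134 counts in all ARLmon/Y libraries and 2 in all WT libraries, a ratio of 495 (95% counting interval 137 to 4095). Cadm3, Ache, Epdr1, Aqp5, Bcan and Fam115a followed, with log2 fold changes of 7.59 to 5.97. The largest falls after Ptgds were those of Lcn2, a lipocalin (-5.13), 3 kallikreins of the Klk1b family that share sequence and are uncertain one by one (Klk1b21, Klk1b27 and Klk1b24, -4.93 to -4.22), and Cby3, Frat1 and Tssk6 (-4.80 to -4.37). Amh, Zbtb16, Cirbp and Rbm3 were at 1.92, 1.02, 0.70 and 1.08 and Gdnf at 0.92 (edgeR's quasi-likelihood test, adjusted p from 5.8e-05 to 0.00786), of which Cirbp and Gdnf turned to -0.08 and -0.01 scaled on the Sertoli cell list. Under that scaling the calls of Zbtb16 and Rbm3 ended (0.10 and 0.21).

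In all, 7821 genes were higher and 6418 lower in ARLmon/Y than in WT by edgeR's quasi-likelihood test, and 4397 and 4002 of them changed at least 2-fold. Without ARLmon/Y library a and AR-/Y library a the counts were 7728 and 6762. The share of higher genes among the calls, 54.9%, was 44.7% with DESeq2's size factors, 73.7% without scaling beyond total counts and 21.9% with scaling on the Sertoli cell list, which moved the median of all genes by -0.24, 0.50 and -0.79.

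In AR-/Y testes, transcripts from late meiosis onwards fell far below WT, and those of most somatic cell lists and, unless scaled on the Sertoli cell list, of spermatogonia rose. Prm1 fell from 2424 ± 953 CPM in WT to 1.93 ± 1.88 CPM (SD, n = 5 each, log2 fold change -10.30, SE 0.92) and Tnp1 from 2765 ± 776 to 3.61 ± 3.92 CPM (-9.59, SE 0.85), with adjusted p = 3.4e-08 and 3.3e-08 by edgeR's quasi-likelihood test. Rhox5 fell 29.9-fold (0.550 ± 0.150 against 16.8 ± 4.91 CPM), and Corin, a protease on the androgen-responsive Sertoli list, 24.3-fold (2.38 ± 0.643 against 57.7 ± 4.65 CPM). Hsd3b6 and Hsd17b3 fell 22.3-fold and 20.2-fold, Star rose 9.44-fold (669 ± 55.6 against 70.9 ± 18.9 CPM), and Foxo1 and Stra8 of spermatogonia rose 7.18-fold and 5.77-fold. Corin lies on chromosome 5 (72300025 to 72504473 in mm10) and ran from 1.28 to 2.95 CPM in AR-/Y against 50.3 to 62.0 CPM in WT.

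All measured genes of 3 late germ cell lists fell, also adjusted over the list alone: 25 of elongating spermatids (median -9.43), 26 of round spermatids (-8.30) and 22 of late pachytene and diplotene spermatocytes (-5.88). Camera gave adjusted p = 4.8e-07, 6.6e-07 and 1.2e-06, and adjusted p = 0.569 with an estimated correlation. Meig1 was at -6.83, Zpbp of the acrosome at -5.76, and Ybx2, an RNA-binding protein of spermatocytes, at -6.06 (edgeR's quasi-likelihood test, adjusted p from 2.7e-09 to 3.6e-09). Of 25 meiotic prophase genes 19 fell and 3 rose (median -0.995, camera, adjusted p = 0.0362, and adjusted p = 0.630 with an estimated correlation), with Syce1 at -4.22 and Prdm9 at 1.80 (0.24 and no longer called scaled on the Sertoli cell list). Of 22 spermatogonial genes 16 rose and 3 fell (median 1.19, camera, adjusted p = 0.0388, and adjusted p = 0.569 with an estimated correlation), and scaled on the Sertoli cell list that median turned to -0.38 and the call ended (adjusted p = 0.114 by camera). The counts of both were equal adjusted over the list alone. In AR-/Y library a, the one with albumin mRNA, the late pachytene score was 3.44 mean log2 CPM against 1.63 to 2.07 in the other 4.

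Of 30 Sertoli cell genes 25 rose and 5 fell (median 2.26, camera, adjusted p = 2.8e-04, and adjusted p = 0.569 with an estimated correlation), with Inha at 3.51, Cst12 at 2.77 and Ptgds at -8.12. The androgen-responsive Sertoli genes held 4 higher and 7 lower of 12 and did not pass (median -1.34, camera, adjusted p = 0.340). Other somatic lists that rose were macrophage (18 of 19, median 2.03), endothelial (12 of 13, 2.75), extracellular matrix (16 of 18 and 1 lower, 2.96), peritubular myoid cell (11 of 13 and 2 lower, 1.72), p53 targets (11 of 18 and 3 lower, 1.68) and retinoid metabolism (13 of 16 and 3 lower, 1.97), with adjusted p from 8.4e-05 to 0.0388 by camera and adjusted p = 0.569 with an estimated correlation. Examples were Lum, a matrix proteoglycan, at 5.501, Kdr, a receptor for endothelial growth factor, at 2.88, and Stra6, the retinol transporter, at 4.06, while Actg2 on the myoid list was at -4.85. AR-/Y libraries d and e were the highest of that genotype in the adipocyte score (4.78 and 4.14 against 1.04 to 3.01 mean log2 CPM), the matrix score (6.92 and 6.79 against 6.47 to 6.62) and the myoid score (5.65 and 5.40 against 4.84 to 5.18), where WT ran from 0.155 to 1.82, from 3.88 to 4.09 and from 4.23 to 4.51. All counts were equal adjusted over the list alone. The calls of meiotic prophase, spermatogonia, steroid synthesis, peritubular myoid cell, p53 targets and retinoid metabolism ended without scaling beyond total counts (adjusted p from 0.0771 to 0.184 by camera).

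Of the steroid synthesis list 11 genes rose and 3 fell of 14 (median 2.23, camera, adjusted p = 0.0388), and of the fetal or immature Leydig cell list 13 of 14 rose (2.73, adjusted p = 2.8e-04), with equal counts adjusted over the list alone and adjusted p = 0.569 with an estimated correlation. Thbs2 and Hsd3b1 of the immature list were at 4.70 and 4.35. Cyp17a1 rose 1.82-fold (417 ± 128 against 230 ± 32.2 CPM, log2 fold change 0.86, SE 0.27), but turned to -0.70 scaled on the Sertoli cell list. The adult Leydig cell list did not pass (7 higher and 9 lower of 16, median -0.76, camera, adjusted p = 0.657), and its median was 0.01 without scaling beyond total counts. Cholesterol genes went both ways, with 13 higher and 7 lower of 22 (median 0.81, or -0.75 scaled on the Sertoli cell list, camera, adjusted p = 0.286). Msmo1 rose by 2.65 on the log2 scale, while Fdft1, the squalene synthase, and Sqle, the squalene epoxidase, were at -3.40 and -2.00. Junction genes (median 0.97, 10 higher and 4 lower of 15), heat shock proteins (-0.09), mitotic cell cycle (-0.29), lymphocyte (0.09), epididymis (-3.54), adipocyte (3.16, 8 higher and none lower of 9), skeletal muscle (-0.86) and red blood cell (1.51) did not pass, with adjusted p from 0.0780 to 0.934 by camera. Of these medians, those of junctions, heat shock proteins, mitotic cell cycle, lymphocyte and red blood cell changed sign under another scaling, and camera pointed up for heat shock proteins and mitotic cell cycle, against their medians. The junction list passed with no low-count filter, with only the 2 groups fitted and without both libraries a (adjusted p from 0.0314 to 0.0405 by camera), and the adipocyte list passed scaled on the Sertoli cell list and without AR-/Y library b (adjusted p = 0.0143 and 0.0486 by camera). Adipoq, the fat hormone adiponectin, was at 28.5 and 17.3 CPM in AR-/Y libraries d and e and at 0.663 to 4.35 CPM in the other 3. It was chosen after its values were seen.

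**Figure D2:**
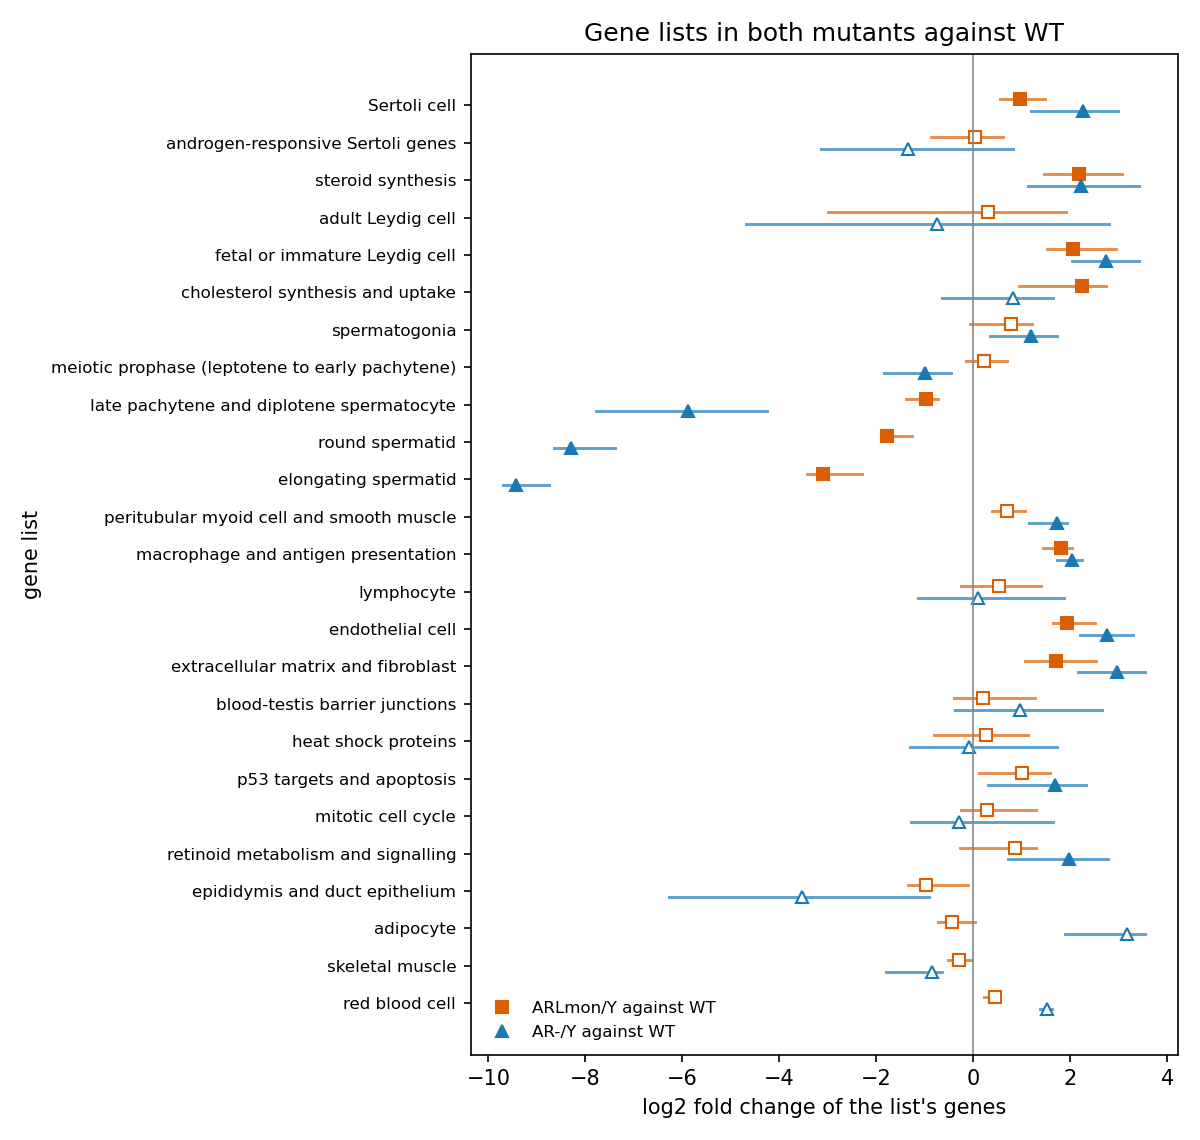
Median log2 fold change of the genes of 25 lists (horizontal axis) in ARLmon/Y (squares) and AR-/Y (triangles) against WT, with lines for the interquartile range over the list's genes and filled markers for an adjusted p under 0.05 by camera with the preset correlation. Elongating spermatid genes lay at -3.11 and -9.43, cholesterol genes at 2.24 and 0.81. Of the filled markers only spermatogonia in AR-/Y (1.19) changed sign under the other scalings that were run.

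Wnt4, a secreted signal of ovary development (chromosome 4, 137277489 to 137299726), rose from 0.470 ± 0.451 to 61.9 ± 9.94 CPM (log2 fold change 7.40, SE 0.56, edgeR's quasi-likelihood test, adjusted p = 7.5e-09). The antisense transcript Foxl2os had 1474 counts in AR-/Y and 1 in WT, a ratio of 1406 (95% counting interval 252 to 55571), and Bpifb4 had 624 and 3 counts, a ratio of 198 (67.6 to 965). In GENCODE vM21, Foxl2os (chromosome 9, 98949781 to 98955299) and Foxl2 (98955288 to 98958543) overlap only at their ends. Only reads of that short stretch could be shared, although the annotation used for the counting is not given. G6pc, H2-Q10 and Ahsg, which are abundant in liver, reached 27.1, 60.7 and 237 CPM in AR-/Y library a, which held albumin mRNA, and 3.99 to 13.1, 13.5 to 20.8 and 13.2 to 13.8 CPM in the other 4, against at most 1.52 CPM in any WT library. Sfrp4 and Bcan rose as in ARLmon/Y (7.23 and 7.16). The largest falls were in genes with almost no AR-/Y counts. Fgf14, Cyb5r2, Ttll2 and Usp46os1 had 0 counts in AR-/Y and were at least 478, 413, 362 and 320-fold lower against 3 counts over the group. Prss51 and Arl13a had 1 count, with WT to AR-/Y ratios of 3920 (703 to 1.55e+05) and 3248 (582 to 1.28e+05), and Znrf4 and Tssk6 were at -11.95 and -11.16. Amh, the anti-Müllerian hormone, Gdnf, Zbtb16 and Rbm3 rose by 3.21, 2.95, 1.78 and 2.02 on the log2 scale, and the call of Zbtb16 ended scaled on the Sertoli cell list (0.20). Sycp3 was at -0.87 (adjusted p = 7.0e-04 by edgeR's quasi-likelihood test), a call that ended without scaling beyond total counts (-0.10) and with limma on the FPKM table (-0.07). Cirbp did not pass (0.11, adjusted p = 0.352 by edgeR's quasi-likelihood test). It was at 0.88 without scaling beyond total counts and at -1.46 scaled on the Sertoli cell list, both past the threshold.

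In all, 8333 genes were higher and 8355 lower in AR-/Y than in WT by edgeR's quasi-likelihood test, with 6358 and 6671 changed at least 2-fold. Without AR-/Y library a and ARLmon/Y library a the counts were 8394 and 8573. The share of higher genes among the calls, 49.9%, was 62.1% without scaling beyond total counts and 20.7% with scaling on the Sertoli cell list, which moved the median of all genes by 0.77 and -1.57.

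Set directly against AR-/Y, ARLmon/Y testes held more transcripts of meiosis, of spermatids and of cholesterol synthesis, and, relative to other genes, fewer of Sertoli, vascular and matrix genes. Prm1 was 78.2-fold higher (150 ± 119 against 1.93 ± 1.88 CPM, SD, n = 5 each, log2 fold change 6.29, SE 0.79) and Tnp1 71.4-fold (6.16, SE 0.74), with adjusted p = 4.4e-06 and 3.1e-06 by edgeR's quasi-likelihood test. Of the androgen-responsive genes, Corin was higher by 4.001 on the log2 scale (38.1 ± 5.23 against 2.38 ± 0.643 CPM), and Rhox5 and Eppin were 4.46-fold and 3.13-fold higher. Cyp17a1 (chromosome 19, 46667165 to 46673172) was 4.02-fold higher (1677 ± 798 against 417 ± 128 CPM), and Wnt4 and Gdnf were at -4.17 and -2.03. Ar itself was 1.74-fold higher (log2 fold change 0.80, SE 0.18, edgeR's quasi-likelihood test, adjusted p = 8.9e-04), a call that ended in the FPKM table (0.40, adjusted p = 0.0629 by limma).

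**Figure D3:**
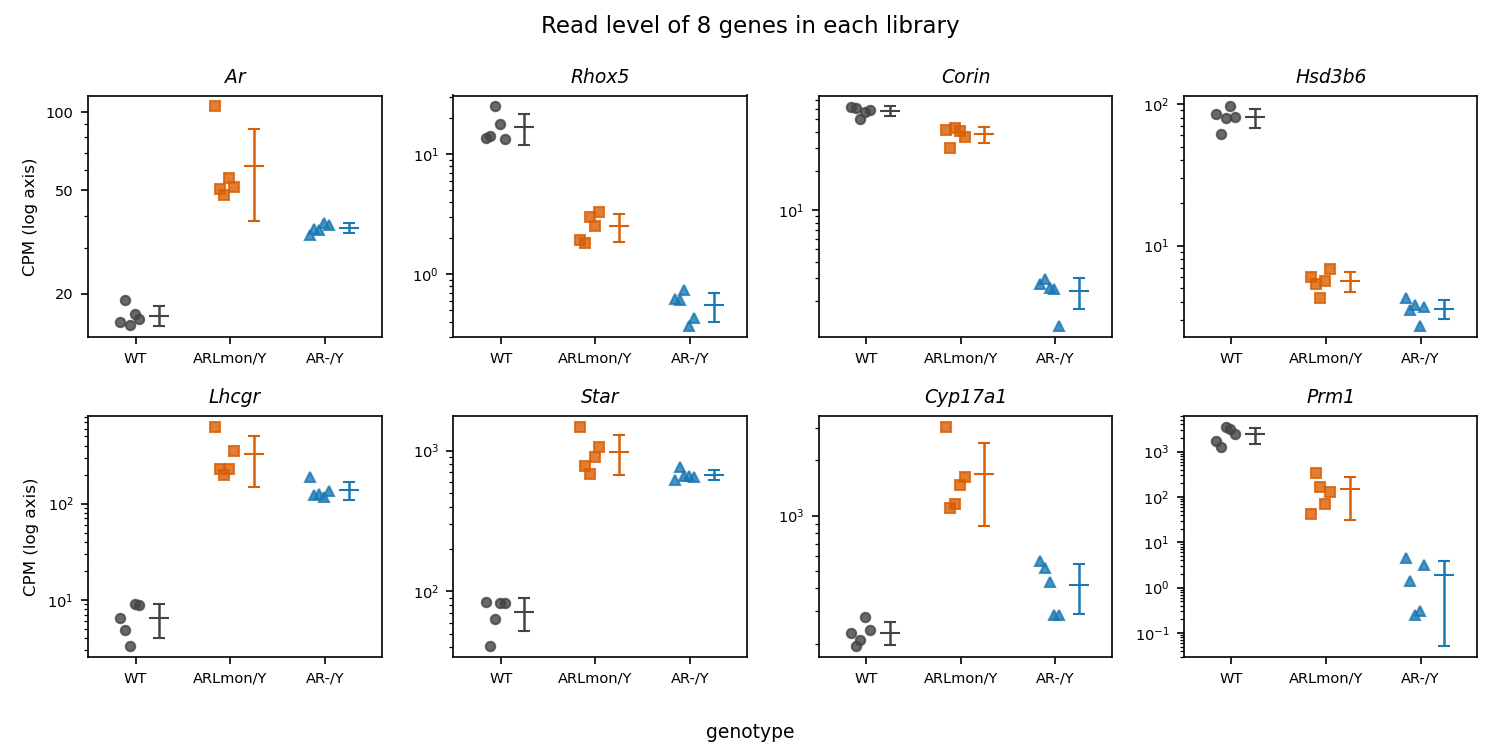
CPM on log axes of 8 genes in each library of the 3 genotypes, with the mean and SD (n = 5) as bars beside the points. Rhox5, Corin and Prm1 stepped down from WT through ARLmon/Y to AR-/Y, whereas Cyp17a1 was highest in ARLmon/Y (1677 ± 798 CPM, with library a at 3052 CPM), and Ar in AR-/Y and Cyp17a1 in AR-/Y lay below WT when libraries were scaled on the Sertoli cell list.

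All 25 elongating spermatid, 26 round spermatid and 22 late pachytene and diplotene genes were higher in ARLmon/Y (medians 6.39, 6.41 and 4.81, camera, adjusted p = 8.7e-08, 5.9e-08 and 5.9e-08), also adjusted over the list alone, with adjusted p = 0.474 with an estimated correlation. Of 25 meiotic prophase genes 21 were higher and 2 lower (median 1.36, camera, adjusted p = 0.00113, and adjusted p = 0.508 with an estimated correlation), among them Spo11, which makes the breaks of meiotic recombination (log2 fold change 3.09, SE 0.26), Syce1 (3.15) and Sycp3 (1.36, SE 0.20). Cholesterol synthesis and uptake was higher in 20 of 22 genes and lower in none (median 1.52, camera, adjusted p = 6.5e-05, and adjusted p = 0.474 with an estimated correlation). Hmgcr, the rate-limiting enzyme of cholesterol synthesis, was at 1.53 (SE 0.09, 250 ± 15.5 against 86.5 ± 10.4 CPM), Fdft1 at 2.48 and Sqle at 2.02. The counts of both lists were equal adjusted over the list alone.

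Lists lower in ARLmon/Y than in AR-/Y were Sertoli cell (23 lower and 4 higher of 30, median -1.17), fetal or immature Leydig cell (9 and 2 of 14, -0.78), peritubular myoid cell (10 and 1 of 13, -0.78), endothelial (11 of 13, -0.70), extracellular matrix (16 of 18, -0.95), junctions (9 and 2 of 15, -0.81), retinoid metabolism (11 and 3 of 16, -1.13) and adipocyte (all 9, -3.22), with adjusted p from 3.2e-05 to 0.00977 by camera. With an estimated correlation they had adjusted p = 0.474, or 0.508 for immature Leydig cell. Adjusted over the list alone the lower genes were 10 for immature Leydig cell and junctions and 12 for endothelial, and equal otherwise. Scaled on the Sertoli cell list, which moved the median of all genes by 0.77, the medians were -0.47, -0.088, -0.100, -0.0038, -0.23, -0.048, -0.42 and -2.45 in this order. The first is of the list that the scaling itself uses, whose mean change is set near 0 by construction, so it tests nothing. AR-/Y libraries d and e were the highest of that genotype in the adipocyte, matrix and myoid scores. The adipocyte score of AR-/Y library b (1.04) lay within the ARLmon/Y range (0.211 to 1.37). Examples were Dlk1 (-2.77) and Thbs2 (-2.52) of immature Leydig cells, Lum (-2.71) and Dcn (-2.03) of the matrix, Jam2 (-1.53) and Tjp2 (-1.17) of junctions, and Stra6 (-2.64). Against its list, the Sertoli cell gene Tsx was higher at 1.44. Spermatogonia (10 lower and 3 higher of 22, median -0.36), p53 targets (10 and 3 of 18, -0.51) and macrophage genes (7 of 19, or 2 adjusted over the list alone, -0.22) passed with adjusted p = 0.0263, 0.0403 and 0.0469 by camera, and had adjusted p = 0.474, 0.474 and 0.682 with an estimated correlation. Scaled on the Sertoli cell list these 3 medians turned to 0.35, 0.21 and 0.49, and each of the 3 calls ended when only the 2 groups were fitted (adjusted p from 0.0707 to 0.159 by camera). Scaling on the Sertoli cell list also ended the p53 and macrophage calls (adjusted p = 0.0737 and 0.561 by camera). The macrophage call also ended without any one of WT libraries b, c and d, ARLmon/Y libraries b, c and e and AR-/Y libraries d and e (adjusted p from 0.0510 to 0.103 by camera), and the p53 call without ARLmon/Y library e (0.0534).

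Steroid synthesis held 6 higher and 5 lower of 14, or 6 and 6 adjusted over the list alone (median 0.15, with camera pointing down, adjusted p = 0.784), and the median was -0.09 without scaling beyond total counts. Hsd17b3 was higher by 1.62 and Cyp19a1, which makes estrogen, by 3.50 on the log2 scale, and Star was at 0.55 (adjusted p = 0.0328 by edgeR's quasi-likelihood test), a call that ended without ARLmon/Y library a (0.35, adjusted p = 0.0763) and with DESeq2 (0.48, adjusted p = 0.0505). Star also missed the threshold without any one of ARLmon/Y library e and AR-/Y libraries a, c, d and e (adjusted p from 0.0570 to 0.0609 by edgeR's quasi-likelihood test). It also ended without scaling beyond total counts (0.30) and with limma on the FPKM table (0.23). Hsd3b6 was at 0.65 (SE 0.16) but at -0.41, not past the threshold, with limma on log2(FPKM + 1). Adult Leydig cell genes held 10 higher and 3 lower of 16 without passing (median 0.94, camera, adjusted p = 0.397), with Vcam1 at 2.73 and Sult1e1, an estrogen sulfotransferase, at 4.99. The androgen-responsive Sertoli genes (median 1.03, 6 higher and 3 lower of 12), heat shock proteins (0.11, or -0.16 without scaling beyond total counts), mitotic cell cycle (0.47), lymphocyte (-0.22, or 0.48 scaled on the Sertoli cell list, mean 0.12), epididymis (2.52), skeletal muscle (0.35) and red blood cell (-1.005) did not pass either (adjusted p from 0.154 to 0.971 by camera). Scaled on the Sertoli cell list the red blood cell list passed (adjusted p = 0.0324 by camera).

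The largest single differences were in genes with almost no AR-/Y counts. Arl13a, Lrrc52, Prss51 and the antisense gene Sox5os3 had 450, 654, 426 and 390 counts in ARLmon/Y and 1, 2, 1 and 1 in AR-/Y, ratios of 412, 299, 390 and 357 whose 95% counting intervals started at 73.6, 82.6, 69.6 and 63.7. Tsga10ip, Znrf4, Adam1b and Cylc1 were higher by 8.21 to 7.81 on the log2 scale. Lower in ARLmon/Y were Asic2 (-4.64), Cdh19 (-4.56), the potassium channel Kcnk3 (-4.50, 6.15 ± 2.56 against 142 ± 16.4 CPM), Wnt4 (-4.17) and Bcat1 (-4.14), besides Itih4, Inmt and Cps1 (-4.90, -4.32 and -4.11). The last 3 were at 61.5, 39.1 and 117 CPM in AR-/Y library a and at 4.03 to 5.69, 4.39 to 7.04 and 4.53 to 8.03 CPM in the other 4. Amh, Zbtb16 and Rbm3 were at -1.28, -0.75 and -0.95, and Cirbp at 0.59 (edgeR's quasi-likelihood test, adjusted p from 1.0e-04 to 0.00694). The calls of Zbtb16 and Rbm3 ended scaled on the Sertoli cell list (-0.10 and -0.25).

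In all, 7993 genes were higher and 5861 lower in ARLmon/Y than in AR-/Y by edgeR's quasi-likelihood test, with 5578 and 2370 changed at least 2-fold, and 8345 and 6851 without both libraries a. The share of higher genes among the calls, 57.7%, was 46.8% without scaling beyond total counts and 86.0% with scaling on the Sertoli cell list, which moved the median of all genes by -0.27 and 0.77.

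Both mutants moved most genes the same way against WT. Of the 18719 genes 13242 were called in the same direction in both, 7147 higher and 6095 lower, and 227 in opposite directions, where independent lists would share 3482 and 2865. The split into higher and lower holds for TMM scaling only. Scaled on the Sertoli cell list, 2969 genes were higher than in WT in ARLmon/Y and 3351 in AR-/Y. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.87 and a covariance of 3.99. Simulated unchanged groups sharing the WT libraries gave r = 0.51, a covariance of 0.0460 and 0 genes called in both (mean of 5 runs). With the WT libraries split between the comparisons, 11412 and 11697 genes were called in the same direction, with covariances of 3.97 and 4.04. In the direct contrast, 9819 of the 13242 (74.2%) were changed more in AR-/Y, 289 more in ARLmon/Y, and 3134 were not told apart. Sycp3 was at 0.49 in ARLmon/Y and at -0.87 in AR-/Y against WT, calls that ended or turned in 8 and 4 of 25 alternatives, and the direct contrast was 1.36 (SE 0.20, adjusted p = 2.2e-05 by edgeR's quasi-likelihood test).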

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

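The tests of mixed RNA and of a wrong label in ARLmon/Y library a, and those of a smaller germ cell share, were chosen after the result was seen, as was the analysis without both libraries a. For the germ cell share, a first test that used the cholesterol list was dropped because 7 of its 22 genes fell in AR-/Y, and the lists were chosen anew. Of 195 groups of 5 libraries, 31 held a library far from the other 4 by Dixon's test, where chance gives about 1 in 20 (9.75). The genotypes' effects were also compared for 55 named genes, and 1 differed in direction.

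AR-/Y library a held transcripts of liver. In 20 liver genes written down before their values were looked at, this library exceeded the other 4 by a median of 6.10 on the log2 scale, and 19 of the 20 were highest in it (1140 CPM in sum against at most 64.0 in any other library, and 2025 CPM of Alb). Of the 20, Apoh, Serpinc1 and Ambp averaged over 1 CPM in WT testis, and over the 20 the other 4 AR-/Y libraries differed from WT by a median of 0.015, which argues against the genotype raising liver transcripts as a set. Liver tissue or its RNA in this library may be the source, although which step brought it in was not tested. Single genes were above WT in the other 4 as well, namely Fgl1, Vtn and Hpx of the 20 (by 2.66, 2.38 and 1.07 on the log2 scale), Cyp2e1 (3.62, chosen after its values were seen), Ahsg, H2-Q10, G6pc, Itih4, Inmt and Cps1. Alb was at 0.122 to 0.552 CPM in these 4 libraries and at 0.117 to 1.28 CPM in WT. This argues against liver RNA as the source of these genes in the 4 libraries. Whether they changed within a cell type or through the cell types present was not tested.

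ARLmon/Y library a lay apart from the other 4 ARLmon/Y libraries. Thinned to the depth of the shallowest of them it stayed apart on the first principal component (92.2 against -85.9 to -29.1), which argues against depth. Of 22 cholesterol genes 21 lay above all 9 other mutant libraries. RNA like that of the other 4 ARLmon/Y libraries, mixed with AR-/Y RNA, could not give this. The RNA of this testis before any mixing was not measured, so a mixture stays open. The late pachytene score of library a lay 4.62 SD above the AR-/Y mean, which argues against an AR-/Y library under this label. No biological explanation was tested, and a difference between the testes sampled stays open. The labels give no batch.

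Its values were 27.9 in 1e6 counts (other 4, 11.8 to 15.996), 5.51 for the immature Leydig score (4.29 to 4.51), 5.57 for late pachytene (7.15 to 7.59) and 6.17 for extracellular matrix (5.37 to 5.45). In CPM they were Ache 35.3 (11.8 to 16.6), Amh 11.3 (3.31 to 5.11), Ar 105 (48.2 to 55.9), Cyp17a1 3052 (1096 to 1617), Epdr1 68.1 (40.9 to 48.7), Fam115a 814 (268 to 390), Foxl2os 5.84 (1.87 to 2.76), Gdnf 5.78 (1.76 to 2.77), Lcn2 8.07 (2.67 to 3.43), Rbm3 42.6 (22.8 to 25.01) and Wnt4 8.11 (1.26 to 2.68).

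Most somatic cell lists were higher in both mutants than in WT by camera with the preset correlation, and none with an estimated correlation (adjusted p = 0.752 in ARLmon/Y and 0.569 in AR-/Y). A smaller share of germ cells would raise every somatic transcript alike, but of the 3 cell type lists that rose with no gene falling, immature Leydig and macrophage moved apart. The immature Leydig list rose by 0.43 more on the log2 scale in ARLmon/Y (1.98 against 1.56) and by 0.88 more in AR-/Y (2.80 against 1.92). Each had p = 0.00794 in a two-sided exact permutation test of 5 against 5 libraries, the smallest that 252 splits can give, or 0.0238 and 0.0119 adjusted over the 3 pairs, whereas the endothelial list was not told apart from immature Leydig and macrophage in ARLmon/Y (adjusted exact p = 0.0595 and 0.302) but was in AR-/Y (0.0119 and 0.0159). This argues against dilution as the whole cause, unless germ cells also hold macrophage transcripts, which was not tested, and a part played by it stays open, as does a change within the somatic cells by genotype.

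The remaining libraries that stood apart were as follows. AR-/Y library a had 11.9 in 1e6 counts (other 4, 12.7 to 12.955), a late pachytene score of 3.44 (1.63 to 2.07) and a round spermatid score of 1.72 (-0.66 to -0.32). In CPM it had Ahsg 237 (13.2 to 13.8), Akr1d1 8.74 (0.183 to 0.367), Cps1 117 (4.53 to 8.03), H2-Q10 60.7 (13.5 to 20.8), Inmt 39.1 (4.39 to 7.04) and Itih4 61.5 (4.03 to 5.69). AR-/Y library b had 765 CPM of Star (620 to 660). WT library d had a Sertoli score of 4.99 (4.85 to 4.88), 19.9 CPM of Cyb5r2 (14.7 to 16.2) and 10.4 CPM of Fam115a (5.19 to 6.40). WT library c had a peritubular score of 4.51 (4.23 to 4.25) and a lymphocyte score of -0.21 (0.38 to 0.48), and WT library a had 13.9 CPM of Usp46os1 (11.3 to 11.9).

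Sycp3 was at 0.49 in ARLmon/Y and at -0.87 in AR-/Y against WT. The first call ended in 7 of 25 alternatives and turned to -0.26 scaled on the Sertoli cell list, and the second ended in 4. Its difference in the direct contrast was 1.36 (SE 0.20, adjusted p = 2.2e-05 by edgeR's quasi-likelihood test).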

How the results depend on the processing

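Leaving out both libraries a was chosen after the data were seen. Of 291 results for named genes 252 kept direction and side of the threshold in every alternative they were tested in (25 for most, 22 to 24 for some), and of 75 list results 54 did so where tested, leaving aside the estimated correlation, with which 0 lists were higher and 0 lower in each of the 3 comparisons. That correlation was 0.85 for elongating and 0.88 for round spermatid genes. With it even the elongating spermatid list in AR-/Y against WT had adjusted p = 0.569 by camera, with all 25 genes lower (median -9.43). A list that misses the threshold in this setting is therefore not shown to be unchanged. Lists were not tested with DESeq2's own test, with limma on the FPKM table or with the added fold threshold, and single genes not with the last. List directions are camera's, and the values are medians less the median of all genes. Medians near 0 change sign in more settings than the test. Leaving out 1 library at a time gave 7600 to 7910 higher and 6029 to 6636 lower genes in ARLmon/Y against WT, 8283 to 8553 and 8321 to 8568 in AR-/Y against WT, and 7741 to 8346 and 5310 to 7029 in ARLmon/Y against AR-/Y. Genes called in the same direction in both mutants numbered 12685 to 13498. In the same order of comparisons, 7, 10 to 11 and 5 lists were higher and 3, 4 and 9 to 11 lower.

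No paired analysis was possible because the columns carry no replicate number, so a fit with a replicate block was not run. Scaling on the Sertoli cell list by construction sets changes relative to the mean log count of those transcripts. In AR-/Y against WT that list had a mean log2 fold change of 1.58 and a median of 2.26, and scaling on its median was not run. The scaling on its mean gave 2969 higher and 10583 lower genes in ARLmon/Y against WT, 3351 and 12835 in AR-/Y against WT, and 12285 and 2007 in ARLmon/Y against AR-/Y. It turned Ar (-0.46), Cyp17a1 (-0.70) and Cirbp (-1.46) in AR-/Y against WT, and Cirbp (-0.076), Gdnf (-0.011) and Sycp3 (-0.26) in ARLmon/Y against WT. It also turned camera's direction for some lists, where the sign of the median in brackets need not follow. In ARLmon/Y against WT that direction turned to up for adipocyte (-0.56) and adult Leydig cell (0.13) and to down for meiotic prophase (0.13). It turned to up for adult Leydig cell in AR-/Y against WT (-0.77) and for steroid synthesis in ARLmon/Y against AR-/Y (-0.074). Without scaling beyond total counts 3750 genes were lower in ARLmon/Y against WT and 5 lists were higher in AR-/Y against WT. Camera's direction for heat shock proteins then turned to down in ARLmon/Y against AR-/Y (-0.0033). DESeq2's size factors turned Cirbp in AR-/Y against WT (-0.080), and DESeq2 itself gave -0.058 for Cirbp. Those size factors turned camera's direction to down for heat shock proteins in AR-/Y against WT (-0.10). They turned it to up for adipocyte in ARLmon/Y against WT (-0.55).

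With a fold change of at least 2 required, which calls fewer genes by construction, 4397 genes were higher and 4002 lower in ARLmon/Y against WT and 2370 lower in ARLmon/Y against AR-/Y. In the FPKM table, 9031, 8811 and 9951 genes were lower in ARLmon/Y against AR-/Y with log2(FPKM + 1), log2(FPKM + 0.1) and no filter, and with no filter 12249 were higher in ARLmon/Y and 13529 in AR-/Y against WT. There Ar in ARLmon/Y against AR-/Y was at 0.40, 0.45 and 0.40 and not past the threshold (limma, adjusted p from 0.0629 to 0.0761), and Hsd3b6 turned to -0.41, -0.49 and -0.41. Camera's direction for the adipocyte list in ARLmon/Y against WT turned to up without both libraries a (-0.43) and without WT library d (-0.23). The median in brackets stayed negative, from -0.79 to -0.23 when 1 library was left out. For heat shock proteins in ARLmon/Y against AR-/Y it turned to down without AR-/Y library b (-0.08) or c (-0.10), over -0.10 to 0.060. For steroid synthesis there camera's direction turned to up with only the 2 groups fitted (0.14). Where no construction is named, the cause was not tested. The WT libraries were the shallowest and deepest, and in simulated counts the fit recovered 11.9% to 22.4% of genes changed 1.5-fold with 5 libraries a group and a variation between libraries of 26.2%. Whether depth or that variation sets this share was not tested.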

Other observations

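The test of granulosa cell genes was written before its genes were looked at, but the spread it was read against, the genes of the ovary and the test of chromosome X with its scalings were chosen after the result was seen.

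Most cholesterol genes were highest in ARLmon/Y of the 3 genotypes. Of 18719 genes 705 were higher in ARLmon/Y than in both WT and AR-/Y, and 351 were lower than in both. Among the 705 were 17 of 22 cholesterol genes (77.3%, against 3.77% of all genes, Fisher's exact test, p = 1.1e-20, adjusted p = 2.8e-19 over 25 lists) and 8 of 25 meiotic prophase genes (32.0%, adjusted p = 3.0e-05). These counts were made only with TMM scaling and all libraries. The meiotic prophase list did not pass camera against WT (median 0.22, adjusted p = 0.677). That median turned negative with DESeq2's size factors and scaled on the Sertoli cell list. The list score of cholesterol genes was 6.67 ± 0.347 mean log2 CPM in ARLmon/Y, 4.78 ± 0.0575 in WT and 5.29 ± 0.261 in AR-/Y (SD, n = 5). Genes of a list are not independent of each other, and steroid synthesis (3 of 14, adjusted p = 0.118) and the list with the lowest p among the 351, spermatogonia (2 of 22, p = 0.0633), did not pass Fisher's exact test.

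X-linked genes had a higher median than autosomal genes in both mutants against WT. The median log2 fold change of 784 X-linked genes was 0.84 in ARLmon/Y and 1.504 in AR-/Y against WT, and -0.57 in ARLmon/Y against AR-/Y, where that of 16837 autosomal genes was 0.10, -0.03 and 0.13. Of the 784, 448, 500 and 181 were higher (57.1%, 63.8% and 23.1%, against 41.3%, 43.8% and 43.5% of autosomal genes) and 200, 210 and 426 lower. Scaled on the Sertoli cell list the X-linked medians turned to -0.031, -0.063 and 0.13, with 0.66, 1.54 and -0.78 left between them and the autosomal medians. Camera gave adjusted p = 0.0147, 1.1e-04 and 9.4e-06, and adjusted p = 0.538, 0.503 and 0.503 with an estimated correlation. The 15 Y-linked genes did not pass camera (adjusted p = 0.809, 0.322 and 0.103).

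Genes known from the ovary, chosen after their values were seen, were higher in AR-/Y than in WT. Esr2 was at 4.49 (7.64 against 0.373 CPM), Fst at 3.90 (20.4 against 1.42 CPM) and Rspo1 at 2.83 (6.11 against 0.844 CPM) on the log2 scale, beside Wnt4 at 7.40 (edgeR's quasi-likelihood test, adjusted p from 7.5e-09 to 6.2e-08). Foxl2 had 42 counts in AR-/Y and 0 in WT and was not tested. One hypothesis was that granulosa cell genes rise as a set. Of 10 such genes 8 were measured, 7 higher and 1 lower (Irx5, -5.55). Amhr2, Irx5, Fzd1, Lhx9 and Runx1 averaged over 1 CPM in WT testis (164, 10.4, 3.85, 3.72 and 1.01 CPM). The median of the 8 genes was 1.89, or -0.37 from that of the Sertoli cell list. This met the bound written against the hypothesis, a median less than 0 above the Sertoli list. The value lies within a margin set from the standard error of the 8 genes' mean (their SD was 3.33). That margin was applied after the value was seen, and the hypothesis stays open.

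The number of called genes was set against other groupings of the 10 libraries of a comparison. With only the 2 groups fitted, the real splits called 13184 genes in ARLmon/Y against WT, 16352 in AR-/Y against WT and 12698 in ARLmon/Y against AR-/Y. In each comparison 1 of 100 splits of the 10 libraries, the real one, called as many. The highest of the others called 0, 0 and 9930. The last put ARLmon/Y library a with AR-/Y libraries b to e on one side, and so exchanged both libraries a, which leaves open the part of each. Every split but the real one mixes the genotypes on both sides, which widens the spread within a side. Few calls were therefore likely beforehand, and the splits cannot tell how many genes would be called by chance.

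Crisp1, an epididymis gene chosen after its values were seen, was at 100.3 CPM in WT library c, at 22.9 CPM in WT library b and at most 11.2 CPM in the other libraries.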
